A study of Irpex lacteus with 14 samples.

How the data were processed

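The series measured messenger RNA by sequencing in mycelium of Irpex lacteus, a white-rot basidiomycete fungus of the order Polyporales, after 3 days at 30 °C in shaken liquid cultures of 100 ml. Per the labels' protocols, 14 libraries were made: 3 each on maltose, cellulose (Avicel, a microcrystalline cellulose), wheat straw and aspen, and 2 on pine. The maltose medium held 20 g per litre of maltose. The cellulose, straw and pine media held 2.5 g per litre of maltose and 15 g per litre of the solid. The aspen medium held 15 g per litre of wood, and its maltose level is not legible in the label. Straw and pine were sieved to fragments under 2 mm, and aspen was milled to 1 mm. The solid media therefore differ from the maltose medium in the level of free sugar as well as in the added solid, and aspen differs from pine in how it was ground. Libraries were prepared from polyadenylated RNA and sequenced as paired ends, per the labels' protocols.

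The authors deposited 1 normalized log2 read count per gene and substrate, per the file headers. TopHat2, HTSeq and DESeq (version 1.5) are named in the submitters' processing notes, with no role, order or parameters. The genome build, the annotation version, the strand setting, the size factors, any value added before the logarithm and any shrinkage are not given in the sources used here. It is also not given whether a substrate's value is the mean of its libraries' log2 values or the log2 of their mean. The headers point to the MycoCosm portal of the Joint Genome Institute for the gene IDs, and each gene is identified by a number only. No genome, gene names or functions were used here, so no gene is given a position, a name or a function, and the gene lists fixed for carbohydrate-active enzymes, peroxidases, laccases, transporters and other groups could not be filled.

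The table held 1000 rows and 977 different gene IDs. The other 23 rows repeated an ID with identical values in every column and were dropped. How the genes in the table were selected is not given in the sources used here, and it is not assumed that they represent the whole genome. The values ran from 0.30 to 17.31 on the log2 scale, and 0 values equalled 0. Values per library, read counts and library totals were not analysed here, so the depth of each library is unknown, no replicate spread could be computed, and no interval, standard deviation or p-value is given for a gene.

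The choices below were fixed before the data were examined, except where stated. Limma's moderated test had been planned on values per library, with a call at an adjusted p under 0.05 and a minimum 2-fold difference. It could not be fitted, since each substrate had 1 value per gene. Only the size criterion was kept: a gene was counted as higher or lower when its log2 values differed by at least 1, and counts at a difference of at least 2 (4-fold) are given beside them. The F-test over the 5 substrates was replaced by the range of a gene's values over the substrates. Genes were kept when the normalized count reached 10 in at least 2 of the 5 substrates, which removed 10 genes and left 967. The rule for named genes gave the 2 genes with the largest positive and the 2 with the largest negative difference in each of the 10 comparisons, which named 21 different genes. The rule had also required a gene to pass the test and its libraries not to overlap, and the filter had been set for 2 libraries: without values per library these conditions were dropped or applied to the substrates instead. These replacements were chosen after the form of the table was known.

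Comparisons against the same maltose value share its error. To show what that alone can do, 100 tables with no difference between substrates were simulated. Their noise per column was set to an SD of 0.41 (log2), which is what would be needed if the whole central spread of the cellulose minus maltose differences (scaled median absolute deviation of 0.57) were error. This spread limits only the combined noise of the cellulose and maltose values of a typical gene. It was split equally between them, so either column alone could exceed 0.41. Comparisons with straw, aspen or pine had larger central spreads, such as 0.67 for aspen minus cellulose, 0.84 for aspen minus pine and 0.85 for straw minus pine. These limit the noise of those columns less tightly. In these tables, a single comparison placed 78.35 genes past 2-fold and 0.58 genes past 4-fold on average. For overlaps between lists, the simulated lists were given the observed sizes by taking the genes with the largest simulated differences, which was chosen after the results were seen. The counting functions were tested on other simulated data for the 967 genes, with noise far below an SD of 0.41. All 600 genes raised by 3 on the log2 scale in pine against maltose were recovered with 0 wrong calls, as were all 200 genes simulated in each of the 2 sets described in the results. With such noise this could hardly fail, so it checks the counting only and says nothing of how accurate the calls are. The alternatives tried were no filter, a stricter filter (mean log2 value of at least 5), 8 added to the linear values, quantile normalization, centring each substrate on its median, and the 4-fold minimum. Counting the repeated IDs again was added after seeing the data. Calculations used Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.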

Results

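Transcript levels of Irpex lacteus were compared after 3 days of growth on maltose, on microcrystalline cellulose, and on 3 ground plant materials: wheat straw, aspen (a hardwood) and pine (a softwood). The series addresses how wood-decaying fungi of the order Polyporales adjust their transcriptome to lignocellulose. For 967 genes, 1 normalized log2 read count per substrate was available, standing for 3 libraries on each substrate except pine, which had 2. No spread between libraries accompanied these values. The differences below are therefore sizes without a test, and a "higher" or "lower" gene is one whose deposited values differed by at least 1 on the log2 scale. The median gene lay at 8.22 on maltose, 8.52 on cellulose, 8.61 on wheat straw, 8.74 on aspen and 8.89 on pine. The median of all genes was thus 0.67 higher on pine than on maltose, which moves the balance of higher and lower genes. The splits after rescaling, and the sizes of the 2 sets of higher genes described below, stand beside the main ones. Rescaling gives the columns a common median or distribution, so it moves these splits by construction and cannot show which scaling is right. Column medians lay 0.30, 0.39, 0.52 and 0.67 above maltose on cellulose, straw, aspen and pine. The median difference per gene was smaller, at 0.03, 0.09, 0.10 and 0.43.

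Most of the genes in the table differed between at least 1 pair of substrates. The range over the 5 substrates reached 2-fold for 708 genes (73.2%) and 4-fold for 312 genes (32.3%). Noise of the size simulated in the processing would place a mean of 392.2 genes past a 2-fold range with no difference between substrates. That size splits the cellulose minus maltose spread equally between 2 columns, and any single column may hold more or less noise. Pine held the highest value of the gene for 326 genes and the lowest for 92, whereas maltose held the highest for 178 and the lowest for 283. These counts depend on the column medians and were not recomputed after rescaling. The levels on maltose were closest to those on cellulose (Pearson's r = 0.89 across genes, which are not independent replicates) and farthest from those on wheat straw (r = 0.77). Among the solid substrates, aspen and pine were the closest pair by this correlation (r = 0.94), followed by wheat straw and pine (r = 0.93). By genes past 2-fold, aspen and cellulose differed least, with 227 genes against 262 for aspen and pine and 297 for straw and pine. That order of the first 2 pairs remained with centring (235 against 246) and turned with quantile normalization (247 against 223).

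**Figure D1:**
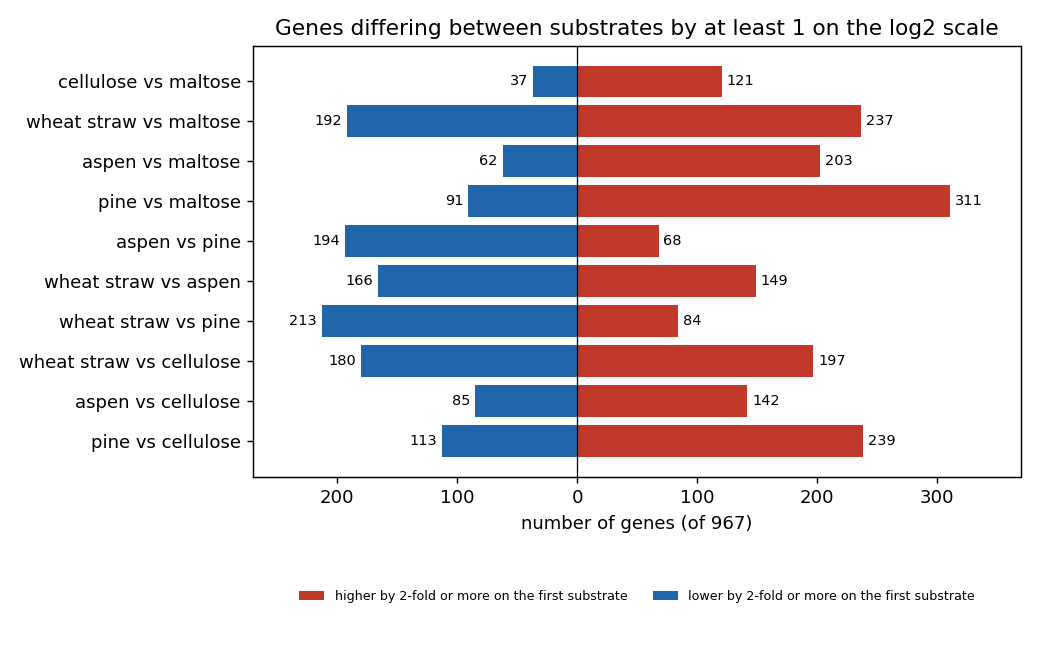
Number of genes, of 967, whose deposited log2 normalized read count was at least 1 higher (red, to the right) or lower (blue, to the left) on the first substrate than on the second, for the 10 comparisons. Cellulose against maltose has the fewest lower genes (37) and pine against maltose the most higher genes (311).

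Growth on cellulose was compared with growth on maltose to show the response to a pure polysaccharide. On cellulose, 121 genes (12.5%) were higher and 37 (3.83%) were lower than on maltose, and at 4-fold the balance was 55 higher and 3 lower. Simulated noise, sized from this same comparison, placed 78.35 genes past 2-fold on average, spread evenly over both directions. The 37 lower genes do not exceed that. This does not show that they are noise, since the simulation counts the whole central spread of these same differences as error and the true noise is unknown. The largest positive differences belonged to genes 1486573 and 1437720. Gene 1486573 had a log2 value of 10.02 on cellulose and 0.37 on maltose, and gene 1437720 had 10.09 and 0.80. These differences of 9.65 and 9.29 rest on maltose values near the floor, and with 8 added to the linear values both came to 6.82. The largest negative differences were small by comparison. Gene 1277977 was 5.11-fold lower (7.37 against 9.72) and gene 1437735 was 4.39-fold lower (9.66 against 11.79). The most abundant gene on maltose, 1596132, was also the most abundant on cellulose, at 17.16 and 17.31. The 10 most abundant genes of both substrates had 9 members in common. The excess of higher genes depended on the scaling: the split became 95 higher and 85 lower with quantile normalization, and 91 and 86 with centring on the median. Centring lowered every cellulose value by 0.30 relative to maltose, although the median difference per gene was 0.03. Part of the added lower genes therefore comes from that shift.

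Wheat straw, a grass material, gave the widest spread of differences from maltose. On straw, 237 genes (24.5%) were higher and 192 (19.9%) lower than on maltose, with 133 and 52 at 4-fold. Gene 1486573 was again the most raised, at 12.58 on straw against 0.37 on maltose, a difference of 12.21 (9.36 with 8 added). Gene 1517890 followed with 10.18 against 0.72, a difference of 9.46 (6.92 with 8 added). The most abundant gene on maltose, 1596132, was 49.2-fold lower on straw (11.55 against 17.16). The gene with the next ID number, 1596133, was lower by a like amount, at 3.21 against 8.74, a difference of -5.53 (-4.66 with 8 added). The 10 most abundant genes held 28.4% of the summed linear values of the table on maltose and 16.8% on straw. Rescaling turned the balance toward lower genes, with 181 higher and 236 lower after quantile normalization, and 174 and 279 after centring.

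**Figure D2:**
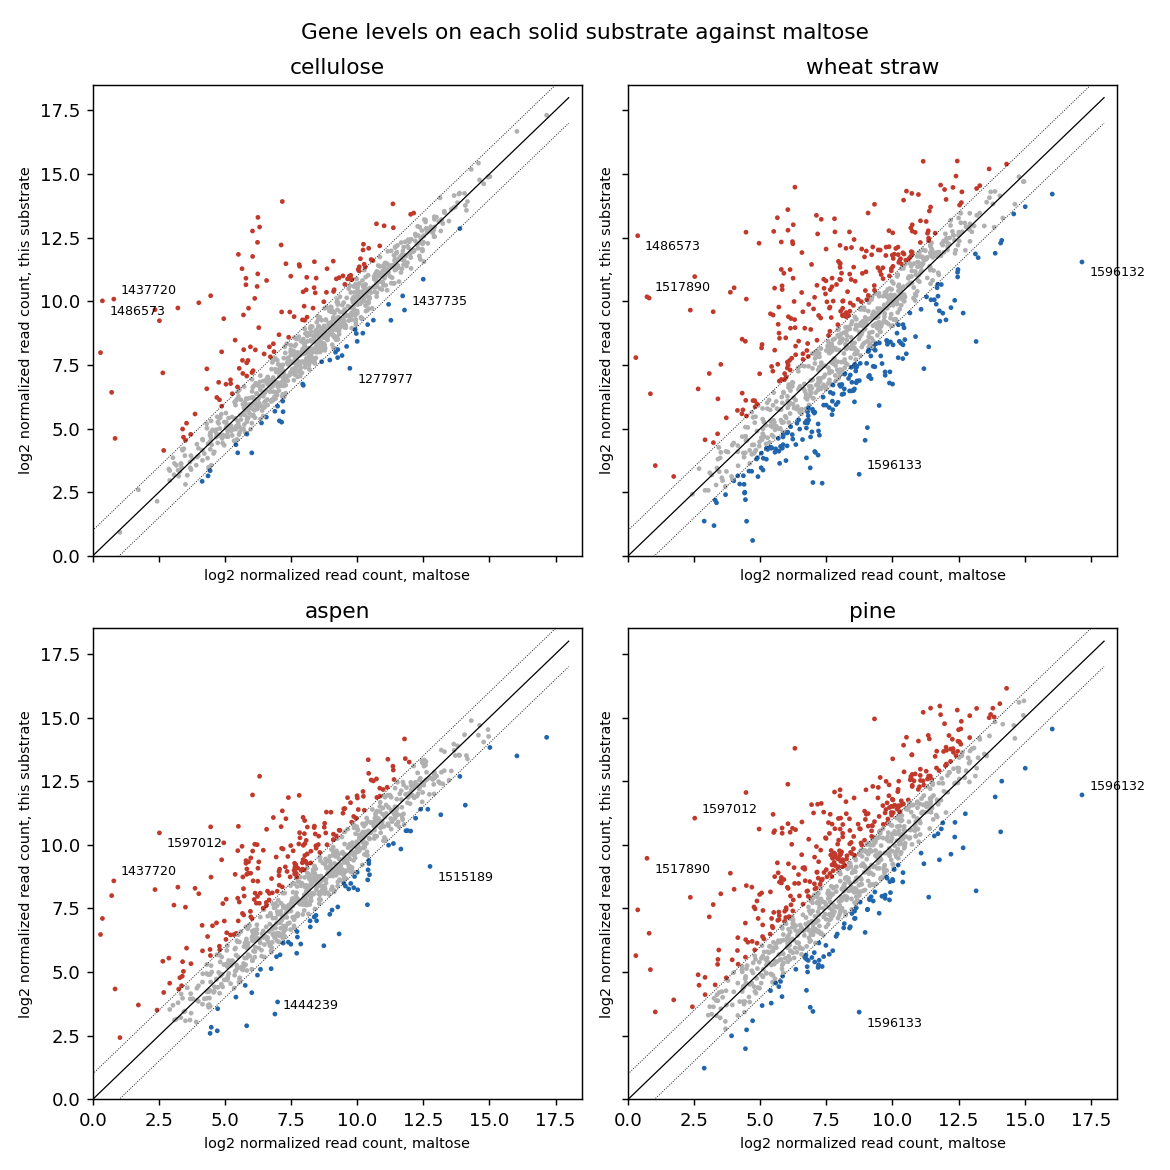
Deposited log2 normalized read count of 967 genes on each solid substrate (vertical axis) against maltose (horizontal axis), each point a gene, with the solid line at equal values and dotted lines 1 above and below it. Red points are at least 1 higher and blue points at least 1 lower than on maltose; the genes named by the size rule carry their ID, and gene 1596132 stands at 17.16 on maltose against 11.55 on wheat straw and 11.96 on pine.

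On aspen, 203 genes (21.0%) were higher and 62 (6.41%) lower than on maltose, with 89 and 11 at 4-fold. The most raised were gene 1597012, at 10.47 against 2.52 (a difference of 7.95, or 6.70 with 8 added), and gene 1437720, at 8.58 against 0.80 (7.79, or 5.33 with 8 added). Gene 1515189 was 12.2-fold lower on aspen (9.15 against 12.76). Gene 1444239 was lower by 3.54 on the log2 scale (3.35 against 6.89), or by 2.80 with 8 added. Gene 1596132, which was 49.2-fold lower on straw, was at 14.22 on aspen. The splits after rescaling were 153 higher and 158 lower with quantile normalization, and 129 and 191 with centring.

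On the deposited scaling, pine gave the most genes above maltose. On pine, 311 genes (32.2%) were higher and 91 (9.41%) lower, with 134 and 20 at 4-fold. Genes 1517890 and 1597012 were the most raised: gene 1517890 was at 9.47 against 0.72 (a difference of 8.75, or 6.22 with 8 added), and gene 1597012 was at 11.05 against 2.52 (8.53, or 7.27 with 8 added). The largest negative differences were those of the same genes as on straw. Gene 1596132 was 36.9-fold lower (11.96 against 17.16), and gene 1596133 stood at 3.43 against 8.74, a difference of -5.31 (-4.54 with 8 added). The median difference from maltose was 0.43 on pine, against 0.03 on cellulose, 0.09 on straw and 0.10 on aspen. With quantile normalization the split on pine became 174 higher and 202 lower, and with centring 176 and 229, where straw had 181 and 174 higher genes, so pine led straw by little or not at all.

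A set of 64 genes (6.62%) was higher on all 4 solid substrates than on maltose. The cellulose, straw and pine media also held less maltose, so an effect of the sugar level cannot be told apart from one of the solids. In this set the median difference from maltose was 3.34 on cellulose, 4.67 on wheat straw, 3.09 on aspen and 3.09 on pine, and 41 of the 64 genes had their largest value on straw. At 4-fold the set held 33 genes, and at 2-fold it held 49 with quantile normalization and 43 with centring. Gene 1486573 and gene 1597012 had smallest differences over the 4 substrates of 6.74 and 6.72, the largest of the set on the deposited values. With 8 added these came to 3.97 and 5.48, and the genes ranked 9 and 3. Only 8 genes were lower on all 4 solid substrates. Lists of the observed sizes, drawn from simulated tables in which only the shared maltose value relates the substrates, had 33.7 higher genes in common on average and 49 at most. For lower genes they had 5.57 on average and 11 at most, so the 8 genes do not stand out against these lists. Every column had the same noise in the simulation, and a noisier maltose column would give larger overlaps in both directions. At the 2-fold cut-off itself, the simulated tables had at most 6 genes in either direction. Their plant-material lists were shorter than the observed ones there, so neither comparison decides whether the 8 lower genes exceed noise.

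A second set of 55 genes (5.69%) was higher on each of straw, aspen and pine than on both maltose and cellulose. These genes were close to the maltose level on cellulose (median difference 0.15), and their median differences from maltose were 2.98 on straw, 1.93 on aspen and 3.06 on pine. On the deposited values the leading member was gene 1583303, at 7.17 on straw, 7.63 on aspen and 7.17 on pine against 3.07 on maltose and 3.19 on cellulose. Its smallest difference from maltose and cellulose was 3.97, or 3.15 with 8 added. It was followed by gene 1587240, chosen after its values were seen, at 10.87, 11.86 and 11.28 on these 3 materials against 7.40 on maltose and 7.52 on cellulose (3.35, or 3.29 with 8 added, which puts it first). A further 19 genes were lower on all 3 plant materials than on both maltose and cellulose. The simulated tables gave at most 1 gene in either set at 2-fold, but their lists past 2-fold were smaller than the observed ones, so this is no matched comparison. The set of higher genes held 42 genes with quantile normalization and 35 with centring.

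By number of genes, the lists that differed from maltose overlapped most among the plant materials. Straw and pine shared 192 higher genes, aspen and pine 159, and straw and aspen 140. Such numbers grow with the sizes of the lists. Independent lists of these sizes would share 76.2, 65.3 and 49.8, and cellulose and aspen shared 80 where independent lists would share 25.4. All overlaps here are on the deposited scaling and were not recomputed after rescaling. For the pairs of plant materials, lists of the same sizes drawn from the simulated tables, which share nothing but the maltose value, shared at most 152, 137 and 117. Among lower genes the same pairs shared 72, 38 and 49, against at most 61, 31 and 44. The simulation gave every column the same noise. A noisier maltose column would give larger overlaps, so these maxima are not the most that a shared maltose value can give. Of the 121 genes higher on cellulose, 80 were also higher on aspen (at most 75 in the simulation), 76 on straw and 78 on pine. The last 2 numbers lie within what the shared maltose value alone gave in lists of these sizes (66.4 and 79.3 on average). So do the 21, 10 and 14 genes that cellulose shared with straw, aspen and pine among its 37 lower genes (22.3, 11.3 and 15.1 on average). Past 2-fold itself, the simulated tables shared at most 19 higher genes for cellulose with straw and 17 with pine. For lower genes they shared at most 17, 15 and 16 with straw, aspen and pine. Noise of that size does not reach the observed sizes of the plant-material lists, so the matched lists do not decide these overlaps. The differences from maltose on straw and on pine had r = 0.83 across genes and a covariance of 2.45, where the shared maltose value alone gave r = 0.50 and a covariance of 0.16 in the simulation. The lowest correlation was that of cellulose and pine, at r = 0.55 with a covariance of 1.07. By ranks (Spearman's rho), cellulose had 0.46 with straw, 0.48 with aspen and 0.46 with pine, none above the simulated r of 0.50. Straw and pine had a rho of 0.76, aspen and pine 0.70, and straw and aspen 0.65. No rho was computed in the simulation. Differences that share no column had r between 0.15 (straw minus maltose with aspen minus cellulose) and 0.64: straw minus cellulose and pine minus maltose had r = 0.64, and straw minus maltose and pine minus cellulose had r = 0.31.

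**Figure D3:**
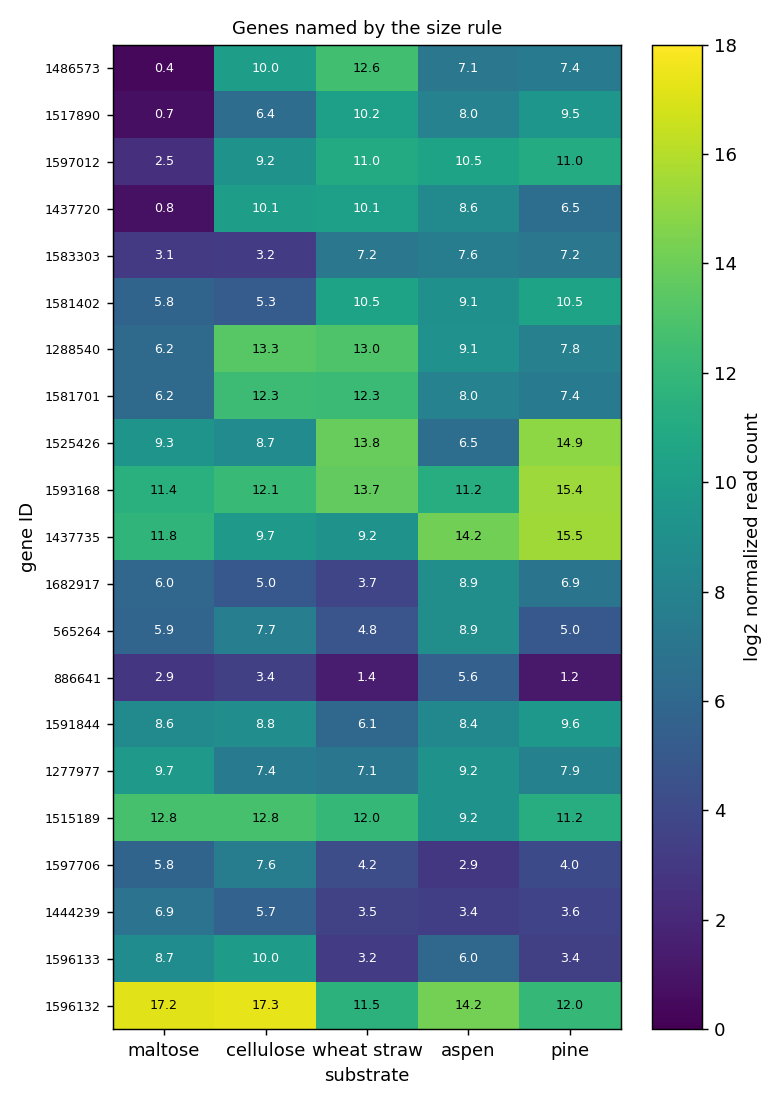
Deposited log2 normalized read count (colour and printed value) of the 21 genes named by the size rule (rows, by gene ID) on the 5 substrates (columns), ordered by the difference between maltose and the mean of the 3 plant materials. Gene 1486573, at the top, goes from 0.37 on maltose to 12.58 on wheat straw, and gene 1596132, at the bottom, from 17.16 to 11.55.

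Aspen and pine were compared to contrast a hardwood with a softwood. On aspen, 68 genes were higher and 194 lower than on pine, with 15 and 35 at 4-fold. Gene 1525426 showed the largest difference in this comparison: it was at 6.50 on aspen and 14.95 on pine, 348-fold lower. It was also abundant on straw (13.81) and stood at 9.32 on maltose and 8.71 on cellulose. Gene 1593168 was 17.6-fold lower on aspen than on pine (11.23 against 15.37). Gene 565264 was 15.0-fold higher on aspen (8.88 against 4.98). Gene 886641 was at 5.55 on aspen against 1.23 on pine, a difference of 4.32 that came to 2.41 with 8 added. The predominance of lower genes on aspen turned with quantile normalization (119 higher and 104 lower) and remained with centring (89 and 157).

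Straw was also compared with each wood. Against aspen, 149 genes were higher on straw and 166 lower, and against pine 84 were higher and 213 lower. Gene 1437735 was the clearest gene of the woods: it was at 15.45 on pine and 14.16 on aspen against 9.22 on straw, 9.66 on cellulose and 11.79 on maltose, so that straw was 75.1-fold below pine and 30.6-fold below aspen. Gene 1682917 was at 3.75 on straw against 8.88 on aspen, a difference of -5.14 (-4.49 with 8 added), and gene 1591844 was 11.6-fold lower on straw than on pine (6.05 against 9.59). In the other direction, gene 1486573 was 44.3-fold higher on straw than on aspen and 35.1-fold higher than on pine, and gene 1525426 was 159-fold higher on straw than on aspen. Gene 1288540 was 36.0-fold higher on straw than on pine (13.01 against 7.84). Neither balance was firm: the split against aspen was 140 higher and 140 lower with quantile normalization and 176 and 138 with centring, and that against pine was 118 and 121, and 122 and 136.

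Each plant material was also compared with cellulose, which had the same load of solid and does not involve the maltose value. On straw, 197 genes were higher and 180 lower than on cellulose, on aspen 142 and 85, and on pine 239 and 113. Gene 1581402 was 36.6-fold higher on straw than on cellulose (10.46 against 5.27), and gene 1525426 was 34.3-fold higher on straw and 75.3-fold higher on pine. Gene 1437735 was 22.6-fold higher on aspen and 55.5-fold higher on pine than on cellulose. Gene 1583303 was higher on aspen by 4.44 (3.59 with 8 added). Gene 1596132 was 54.4-fold lower on straw than on cellulose, and gene 1596133 differed from cellulose by -6.78 on straw and -6.55 on pine (-5.89 and -5.76 with 8 added). Gene 1288540 was at 13.30 on cellulose and 44.0-fold lower on pine, and gene 1581701 was at 12.32 on cellulose and 20.3-fold lower on aspen. Gene 1597706 was at 7.59 on cellulose and 2.89 on aspen, a difference of -4.69 (-3.70 with 8 added). The split on pine became 170 higher and 168 lower with quantile normalization and 170 and 178 with centring, and that on aspen 138 and 109, and 111 and 124. That on straw became 173 and 169 with quantile normalization, and turned to 174 and 199 with centring.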

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

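The direction of each of the 40 differences of named genes stayed the same, and its size stayed at or above 1, in each alternative that kept the gene: no filter, the stricter filter (which kept 37 of the 40), 8 added to the linear values, quantile normalization and centring. This could hardly fail, since the genes were named for their size and the smallest of these differences was 2.13 on the log2 scale. The filters leave the values of a kept gene unchanged, and centring moved a substrate by at most 0.67 relative to maltose. The 13 counts stayed within 1.5 times their main value without a filter, with the stricter filter, with 8 added, with quantile normalization and with repeated IDs counted again. Centring kept 12 of them, and took the genes higher on the 3 plant materials than on maltose and cellulose from 55 to 35. The division into higher and lower genes depends more on the scaling than the counts do. Rescaling moved it by over 10 percentage points in all 4 comparisons with maltose and in 4 of the other 6, and each such split stands beside its comparison. Both rescalings move it by construction, since they give the selected genes a common median or distribution on every substrate. They therefore do not show that the deposited division is wrong, nor which scaling is right. The splits of straw against aspen and against cellulose moved by less, but centring turned both. That of straw against aspen also turned with the stricter filter (144 higher and 138 lower) and with 8 added (144 and 140). A minimum of 4-fold lowered every count by its construction. Against maltose it left 58 genes on cellulose, 185 on wheat straw, 100 on aspen and 154 on pine. Between aspen and pine it left 50, between straw and aspen 100, between straw and pine 67, and against cellulose 137 on straw, 70 on aspen and 138 on pine. It left 33 genes higher on all 4 solid substrates, 11 higher on the plant materials alone, and 312 with such a range over the 5 substrates. No paired analysis was possible because the replicate numbers of the labels are not carried by the table, which holds 1 value per substrate. For the same reason, leaving out each library in turn, fitting only the compared groups, the replicate block, the settings of the variance prior (trend off, robust on) and the fit with no minimum fold were not run, and the correlation setting of the gene-group test was not run since no annotation was used. Genes under about 10 normalized counts on a substrate have differences that depend on the unknown value added before the logarithm: 13 of the 40 named differences involve such a value.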

Other observations

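The tests on genes with neighbouring ID numbers, and the substrate combinations named below, were chosen only after the results were seen; the outcomes that would decide the tests on the pine excess and on the wheat straw and pine genes were fixed before their values were seen, although these patterns themselves had been noticed in the same data. Sorting genes by the substrates on which they lay at least 1 above all the others showed several combinations besides those reported. Wheat straw alone had 40 such genes and pine alone 47, against 14 for cellulose, 13 for aspen and 8 for maltose. Wheat straw with pine had 51, led by gene 1525426. Cellulose with wheat straw had 23, led by gene 1581701, which was at 12.32 and 12.26 on these and at 6.23 on maltose, 7.98 on aspen and 7.40 on pine. Aspen with pine had 14, led by gene 1437735, and wheat straw with aspen had 4. In the other direction, 53 genes lay at least 1 lower on wheat straw than on the other 4 substrates, led by gene 1285067 at 5.04 on straw against 7.44 to 9.05 elsewhere.

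Thus more genes were highest on wheat straw and pine together (51) than on the 2 woods together (14), although aspen and pine had the more similar levels over all genes. Column scaling as the whole cause is argued against, since the difference was still 17 genes after quantile normalization (25 against 8). A weaker response of the same genes on aspen would place aspen above maltose in them. Over the 51 genes, aspen lay above maltose by a median of 0.85 (bootstrap SE 0.24), in 43 of them and by at least 1 in 23, while cellulose lay above it by 0.09 and straw and pine by 2.80 and 2.79. Over all genes the median difference of aspen from maltose was 0.10. With quantile normalization the median of the 51 genes came to 0.48 (SE 0.21), a little under the 0.5 set beforehand, so a weaker response on aspen stays open. That value was computed after the first result was seen, and the SE of each median resamples genes, not libraries. Whether the finer grinding of aspen, its wood chemistry, its maltose level or the batch of its cultures lies behind the lower aspen values was not tested, since each goes with the aspen column.

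Pine values lay above those of the other substrates even where these were level. In the 121 genes whose other 4 values lay within 0.5 of each other, pine exceeded their mean by a median of 0.36 (bootstrap SE 0.09), and in 90 of them. The same measure was -0.14 (SE 0.04) for aspen and within 2 SE of 0 for maltose, cellulose and straw. These SEs resample genes, not libraries, so they leave out any error that a whole column shares. Compression, or the smaller number of pine libraries, that raised low pine values would put the excess in weakly expressed genes. The 41 genes of highest level instead had an excess of 0.53 (SE 0.13), and the 41 of lowest level 0.10 (SE 0.15). These values argue against that form as the whole cause. Compression that drew low values together on all substrates would lessen an excess at low levels, so they do not address it. A single scaling factor of the pine column would give every level the same excess; those of highest level exceeded those of lowest by 0.43 (SE 0.20). The bound fixed beforehand was 0.2 passed by more than 2 SE, and 0.43 passes it by a little over 1 SE. The factor therefore stays open, also because compression at low levels could hide part of its excess there. A scaling factor and an effect of pine itself cannot be told apart here, and neither can the selection of the genes in the table, since the values of unselected genes were not analysed here.

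Genes 1596132 and 1596133, whose IDs follow each other, had parallel profiles over the substrates (r = 0.99) at levels of 17.16 and 8.74 on maltose. If neighbouring IDs in general marked genes with shared profiles, other close pairs would resemble each other too. The 44 pairs with IDs at most 5 apart had a median profile correlation of 0.02 (bootstrap SE 0.10) against 0.07 after shuffling the IDs (1-sided permutation p = 0.657 over 10000 shuffles). This gives no sign of a general relation and does not exclude one. The test was reworded 2 times after its result was seen; a bound of 0.3 on the median, set once the median was known, was dropped. Reads shared between near-identical copies or overlapping gene models were tested on the 3 pairs with r of at least 0.9, where the median difference in mean log2 level was 0.47 (bootstrap SE 3.37) and 2 pairs differed by under 0.5. The other pair was 1596132 and 1596133, at 8.16, far past the bound of 1. That bound was ill chosen for it, since a small share of the reads of a much more abundant gene would also give a parallel profile at a far lower level. With 3 pairs the median decides nothing, and read sharing stays open for all of them. This test was left out when the other was first reworded, and was then put back with its first bounds.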
